A study of Pseudo-nitzschia multiseries
Sulfitobacter sp. SA11 and Sulfitobacter sp. SA11 and Pseudo-nitzschia multiseries with 18 samples.

How the data were processed

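RNA was measured in cultures of the diatom Pseudo-nitzschia multiseries PC9 and the bacterium Sulfitobacter sp. SA11. Per the labels' protocols, diatom cultures grew at 13 °C with 16 h of light and 8 h of dark at 80 µmol photons per square metre and second, and the axenic culture had been made with antibiotics. Co-cultures started at about 4000 diatom cells and 100000 bacterial cells per mL. Temperature and light of the bacterial cultures with glucose are not given in the sources used here. Per the labels' protocols, 2 L of culture were filtered onto a 3 µm filter and the flow-through onto a 0.2 µm filter. Diatom RNA was selected for poly(A) tails, ribosomal RNA was removed with organism-specific probes, and the RNA was amplified linearly before sequencing on a SOLiD version 4 instrument.

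The authors made the gene counts with the SEAStAR package, per the labels. The counts are whole numbers that were not normalized. The genome builds, annotation versions, aligner settings and treatment of reads that match several genes are not given in the sources used here, so genes with near-identical copies or overlapping neighbours can share reads. The authors also deposited log2 fold changes and log2 mean abundance, which per the labels come from edgeR on counts pooled over the cultures of each group, with p-values and their Benjamini-Hochberg adjustment. The bacterial fold changes in the authors' deposited table followed a fit of the separate cultures more closely than pooled counts, so how the authors made them is left open. The edgeR version used by the authors is not given in the sources used here. The 45 diatom genes with 0 counts in all libraries had no defined log2 abundance in the authors' deposited table. Diatom identifiers in that table were lower by a constant than those of the count table. The constant was found from 4641 gene models whose own names carry a number lower by 343 than their identifier, and it was then applied to all identifiers. Which of the 2 numberings other sources use is not given in the sources used here. Diatom genes are named by the identifier of the count table.

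The labels list 18 samples, 6 of diatom and 12 of bacterial transcripts. Each bacterial culture has 2 samples in the labels, a paired-end and a single run, while the count table holds 1 column per culture. Which run a column holds is not given in the sources used here, so columns were tied to the culture and each group had n = 3 cultures. Letters A to C name cultures and were not used as pairs. Pairs of libraries in one group differed by 25.0 to 129 times (bacterium) and 29.4 to 89.4 times (diatom) the variance of counting noise, so no library was a copy of another.

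Counts were analysed in R 4.3.3 with edgeR 4.0.16 as follows. Genes with low counts were left out with filterByExpr, libraries were scaled with TMM factors, and the groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest), separately per organism. Adjusted p-values are from the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The biological coefficient of variation was 20.3% in the diatom and 21.5% in the bacterium. CPM values use the scaled library sizes, with a few exceptions. The summed CPM of the bacterial genes that fell over 32-fold, the median CPM ratios between bacterial co-cultures and the linear positions of the diatom co-cultures use library totals. A standard error is the size of the log2 fold change divided by the square root of its F statistic. Intervals for ratios of summed counts are exact 95% conditional Poisson intervals and cover counting error only, since amplified reads carry no molecular identifiers.

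The tests and samples of both group comparisons and the rule for naming genes were fixed before the data were examined. The rule took, per organism, at most 2 identifiers that rose and 2 that fell, those with the largest log2 fold change among called genes whose groups do not overlap and whose mean is at least 10 CPM in the higher group. That is the part of the rule for tables without product names. Gene lists by function had been fixed for both organisms as patterns on product names. No annotation with product names was used here, so no list was tested, and ribosomal or transfer RNA genes were not set apart.

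Alternatives were DESeq2 1.42.0, median-of-ratios (RLE) factors, total count scaling, no filter, a filter of at least 50 counts in at least 3 libraries, a 2-fold threshold, a block for the culture letter, pooled counts, and leaving out each culture. After the data were seen, an assumed carry-over between bacterial libraries was also subtracted: each library lost the lowest share of the other group's summed counts found among that group's most counted genes. This sets the gene with the lowest share to 0 by construction. The procedure was tested on simulated data with the means, library sizes and dispersions of these libraries and 50 genes, each with an expected count of at least 20, changed at each fold. In the diatom simulation of 14100 genes, edgeR recovered 10% of genes changed 1.5-fold, 40% at 2-fold, 96% at 4-fold and 98% at 8-fold, and 10 of 132 calls were false. In the bacterial simulation of 5146 genes it recovered 10%, 66%, 96% and 100% at the same folds, and 12 of 148 calls were false. In these simulations, changes of 1.5-fold were therefore mostly not recovered with 3 cultures per group. The data gave far more calls, 1266 in the diatom and 4098 in the bacterium, so the threshold of 0.05 admitted larger p-values there. The simulated rates therefore do not carry over to the data, least of all to the bacterial comparison. Runs of consecutive locus tags were counted on tag numbers as given, with gaps ending a run, and set against 1000 shuffles of the order. Figures were drawn with matplotlib 3.10.9.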

Results

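The cultures paired a marine diatom with a marine bacterium. Pseudo-nitzschia multiseries strain PC9 is a chain-forming pennate diatom of coastal waters, and Sulfitobacter sp. SA11 is an alphaproteobacterium that had been isolated from this diatom. Both were grown in Aquil, a defined seawater medium, and harvested in mid-exponential growth. Diatom transcripts were counted in 3 axenic cultures (cultures without bacteria) and in 3 cultures with the bacterium. Bacterial transcripts were counted in 3 cultures given 1 µM glucose in place of the diatom and in 3 cultures with the diatom. The counts covered 16822 diatom gene models and 5230 bacterial genes. Libraries of the axenic diatom held 28130987, 24577699 and 33066879 counts for cultures A, B and C, and those of the diatom with the bacterium held 20426283, 35315112 and 18983811 counts. Libraries of the bacterium with glucose held 10362751, 10057584 and 9411179 counts, and those of the bacterium with the diatom held 1860978, 10275972 and 5487774 counts. Bacterial co-culture A was thus 0.181 times as deep as co-culture B.

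Within a group, libraries ranked genes alike, with Spearman correlations across genes of 0.977 to 0.989 in the diatom and 0.965 to 0.991 in the bacterium. Between groups the correlations were 0.951 to 0.979 in the diatom and 0.590 to 0.662 in the bacterium. Genes are not independent replicates, so these values describe the libraries and carry no p-value. The first principal component of log2 CPM (counts scaled to a common library total) held 48.5% of the variance among diatom libraries and 92.2% among bacterial libraries. It parted the groups in both organisms. Diatom co-culture A lay at 9.30 on that component, between the axenic cultures at -40.3 to -26.1 and co-cultures B and C at 37.1 and 46.4.

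**Figure D1:**
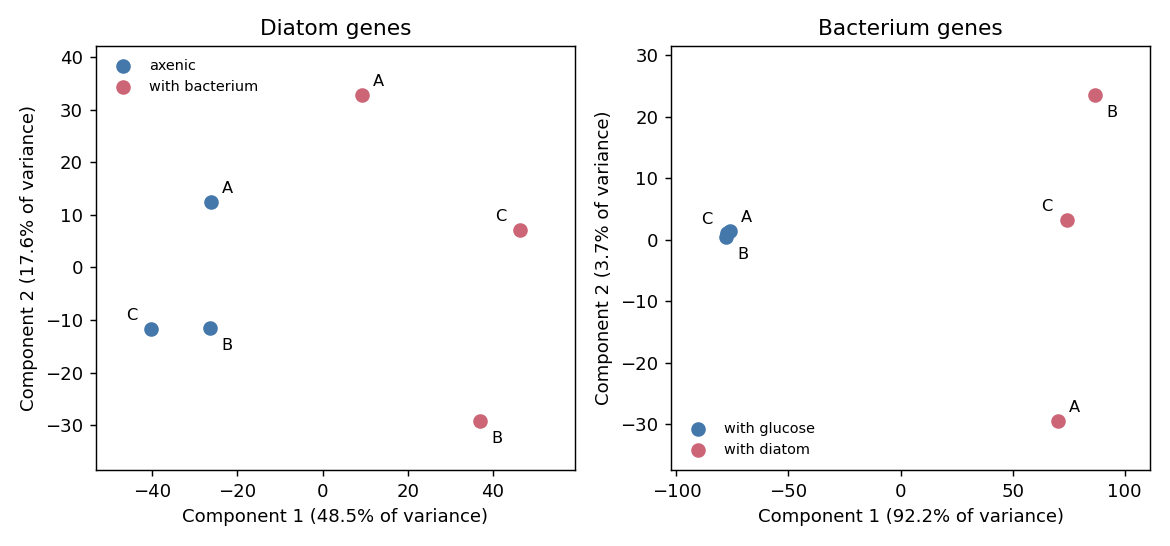
First and second principal components of log2 CPM, with 1 point per culture and letters for the culture, for diatom genes on the left and bacterial genes on the right. The glucose cultures of the bacterium fall together, at -77.7 to -75.9 on the first component, and diatom co-culture A lies at 9.30, nearer to the axenic cultures than co-cultures B and C are.

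The first comparison asked which diatom genes change in transcript abundance when the bacterium is present. Of 14100 gene models tested, 1266 (8.98%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, with 449 higher and 817 lower in the presence of the bacterium. Most called changes were under 2-fold. The median size of a called change was 0.92 on the log2 scale, and 521 called genes changed at least 2-fold, with 149 higher and 372 lower. In 32.6% of the tested genes the 3 values of one group all lay above the 3 of the other, against 10% by chance. Genes with names of the fgenesh1_kg class, 1 of 8 classes of gene model, were mostly higher among those called, with 151 higher and 70 lower, a direction opposite to the other classes combined, with 298 higher and 747 lower. That split was looked at only after the calls were seen. With total count scaling, 224 genes were called higher and 717 lower, so the share of calls that were higher was 23.8% against 35.5%. The number of called genes rested on single cultures: it was 566 without axenic culture A, 265 without axenic culture B and 342 without axenic culture C. It was 2290 without co-culture A, 790 without co-culture B and 220 without co-culture C. DESeq2 called 2138 genes, 1259 of them among the 1266 and in the same direction.

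Among called diatom genes with at least 10 CPM in the higher group and no overlap between groups, the largest rise was in gene model Psemu1|283562. It rose from 10.3 CPM ± 3.12 (SD, n = 3) in axenic cultures to 79.9 CPM ± 45.5 (SD, n = 3) with the bacterium, a log2 fold change of 2.95 with a standard error of 0.376 and an edgeR adjusted p of 0.0052. Psemu1|302307 rose from 16.8 CPM ± 6.46 to 75.1 CPM ± 32.4, by 2.16 on the log2 scale (SE 0.328, edgeR adjusted p = 0.00806, n = 3). Psemu1|66582 had the largest fall, from 221.7 CPM ± 48.9 to 36.9 CPM ± 5.65, a log2 fold change of -2.59 (SE 0.198, edgeR adjusted p = 0.000864, n = 3). Psemu1|193070 fell from 17.7 CPM ± 0.835 to 3.69 CPM ± 0.822, a log2 fold change of -2.25 (SE 0.213, edgeR adjusted p = 0.00174, n = 3). All 4 stayed past the threshold without any 1 of the 6 cultures. The highest value of both risen genes was in co-culture A. The tables analysed pair no product names with these identifiers, so what the genes encode is not stated. Diatom identifiers are those of the count table, and the authors' deposited table numbers the same gene models differently, so a number looked up elsewhere could point to another gene model.

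The second comparison asked which bacterial genes differ between growth with the diatom and growth on glucose. Temperature and light are not given for the glucose cultures, so a difference in them cannot be told apart from that of the diatom. No bacterial culture lacked both glucose and the diatom, so a rise with the diatom cannot be told apart from a fall on glucose. Most of the bacterial transcriptome differed. Of 5146 genes tested, 4098 (79.6%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 1957 higher and 2141 lower with the diatom. The median called change was 1.85 on the log2 scale. At least 2-fold changes were called in 3394 genes, with 1623 higher and 1771 lower. Changes of at least 8-fold numbered 480 higher and 328 lower, and changes of at least 32-fold 99 higher and 25 lower. In 81.4% of the tested genes the values of both groups did not overlap, against 10% by chance. The 1957 genes called higher held 13.7% ± 0.585 (SD, n = 3) of the counts on glucose and 78.8% ± 2.85 (SD, n = 3) with the diatom. The 2141 genes called lower held 75.1% ± 1.08 of the counts on glucose and 12.4% ± 2.37 with the diatom (SD, n = 3 each). The median log2 fold change over all tested genes was -0.12 with the scaling used and -0.49 with total count scaling, so fold changes are relative to that centre. With total count scaling 1658 genes were called higher and 2426 lower, and with RLE factors 2041 were called in each direction. The number called was 3827 to 4047 when any 1 culture was left out.

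**Figure D2:**
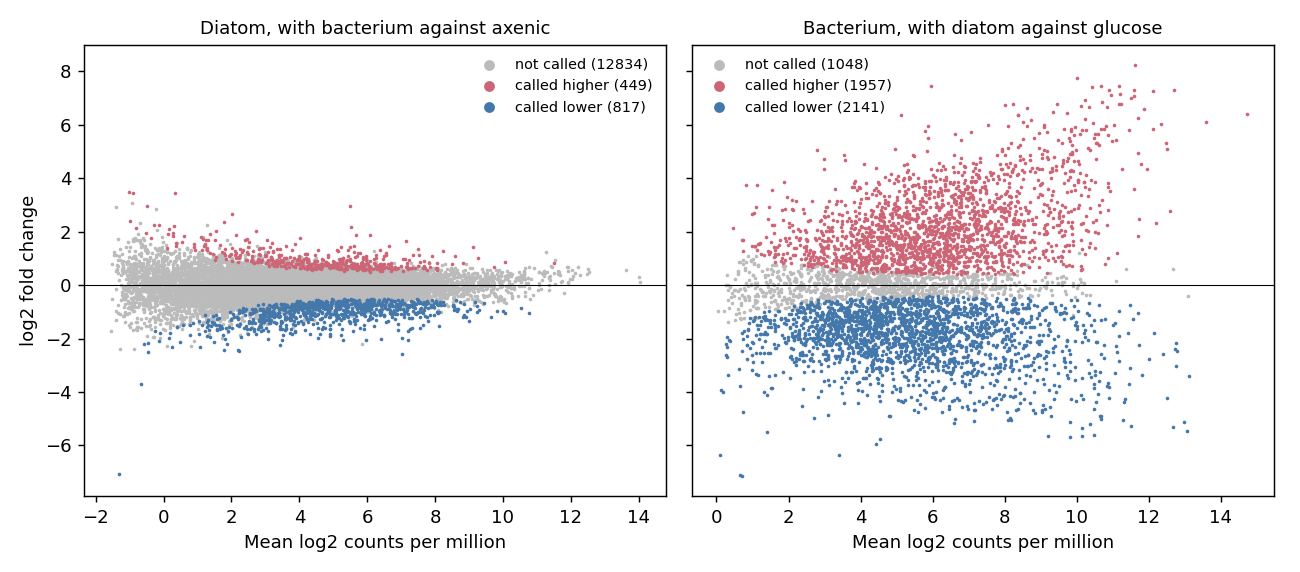
log2 fold change against mean log2 CPM for every tested gene, diatom on the left and bacterium on the right, with genes called higher in red, called lower in blue and not called in grey. Called diatom genes number 449 higher and 817 lower, and called bacterial genes 1957 higher and 2141 lower.

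Among called bacterial genes chosen by the same rule, SA11v2_00632 rose most. It had 21.0 CPM ± 1.43 (SD, n = 3) on glucose and 6312 CPM ± 1520 (SD, n = 3) with the diatom, a 300-fold rise with a log2 fold change of 8.23 (SE 0.336, edgeR adjusted p = 5.53e-08). SA11v2_00630 rose from 9.58 CPM ± 0.788 to 2073 CPM ± 604, by 7.75 on the log2 scale (SE 0.321, edgeR adjusted p = 5.61e-08, n = 3). The counts of SA11v2_00632 in each glucose library were 0.251%, 0.215% and 0.214% of its summed co-culture counts, the lowest such shares in those libraries among the most counted co-culture genes, so its level on glucose would not be resolved if libraries shared counts at that rate. With those shares subtracted as assumed carry-over, an alternative chosen after seeing the data, 0 of the 708 glucose counts of SA11v2_00632 and 88 of the 323 of SA11v2_00630 were left, and the log2 fold change of SA11v2_00630 was 9.65. Under that rule SA11v2_03903 and SA11v2_03904 fell most. SA11v2_03903 had 605 counts summed over the glucose cultures and 3 over the co-cultures, a ratio of pooled counts per library total of 119.1 with a 95% counting interval of 40.6 to 579.4. Its fall in the edgeR fit was 82-fold (edgeR adjusted p = 1.57e-06, n = 3). SA11v2_03904 had 1305 and 9 counts, a ratio of 85.7 with a counting interval of 44.99 to 187.8, and fell 61.1-fold in the edgeR fit (edgeR adjusted p = 2.24e-07, n = 3). These intervals cover counting error only. With carry-over subtracted in the same way, 1 co-culture count of SA11v2_03903 and 3 of SA11v2_03904 were left, and the fitted log2 fold changes were -7.75 and -7.46. The subtraction assumes that counts were shared and does not show it. It also used the lowest shares. The 18 abundant genes (log2 CPM above 5) that fell over 32-fold had 0.293%, 0.240% and 0.205% of their glucose counts in co-cultures A, B and C. If libraries shared counts at those rates, the level of SA11v2_03903 and SA11v2_03904 with the diatom would not be resolved. The fitted log2 fold change of SA11v2_03903 was -6.36 with all cultures, -7.60 without co-culture A and -5.75 without co-culture C, and that of SA11v2_03904 was -5.93 with all cultures and -5.23 without co-culture B.

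**Figure D3:**
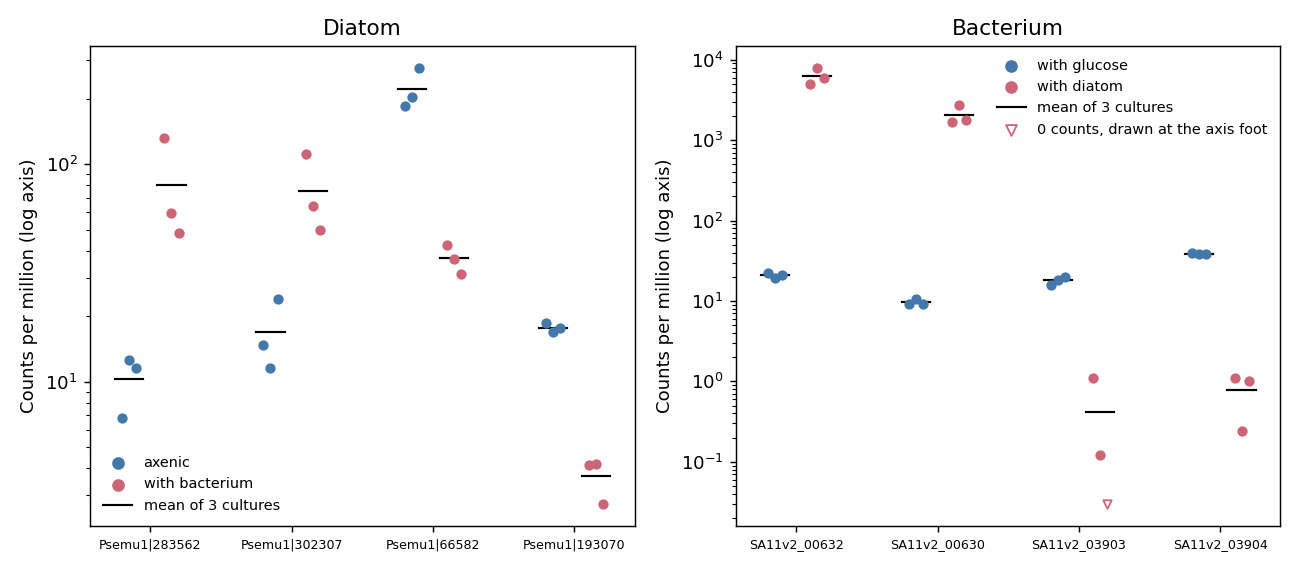
CPM of each named gene on a log axis, with 1 point per culture, bars at the mean of 3 cultures, control cultures in blue and co-cultures in red. Groups do not overlap for any of the genes, and the open triangle is a library with 0 counts of SA11v2_03903.

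Bacterial genes with consecutive locus tag numbers changed together. Runs of 5 or more consecutive tags in which every gene was called in one direction and changed at least 2-fold numbered 202, of which 100 were higher and 102 lower. They held 1554 genes, 45.8% of the 3394 called at least 2-fold. When the order of the tags was shuffled 1000 times, the mean was 25.1 runs and 137 genes, and the permutation p of 0.001 was the smallest that these shuffles can give. The longest runs had 26 genes, against at most 16 after shuffling. Tags 1660 to 1685 were all higher, with a mean log2 fold change of 1.92, and held 0.296% ± 0.0338 of the counts on glucose and 0.927% ± 0.0831 with the diatom (SD, n = 3). Tags 2308 to 2333 were all lower, with a mean log2 fold change of -1.97, and held 0.237% ± 0.00693 and 0.0471% ± 0.00671. The 11 genes of tags 625 to 635, among them both named genes that rose, had a mean log2 fold change of 6.80 and together rose from 0.0424% ± 0.00196 to 3.90% ± 0.592 of the counts, a ratio of the means of 92. With the assumed carry-over subtracted, 7639 of the 12640 glucose counts of this region were left and the ratio was 154. The 7 genes of tags 4322 to 4328 fell, with a mean log2 fold change of -3.77. Runs and regions were chosen after the fold changes were seen, and whether tag numbers follow the chromosome is not given in the sources used here.

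**Figure D4:**
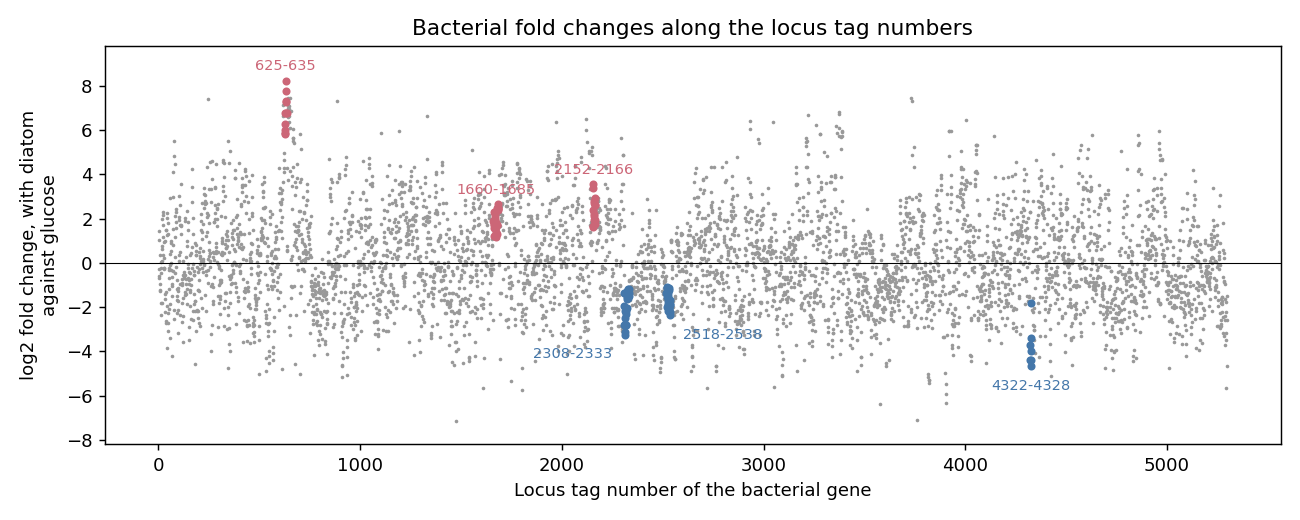
log2 fold change of each tested bacterial gene, with the diatom against glucose, along the locus tag number, with 3 regions of higher genes in red and 3 of lower genes in blue, each marked with its first and last tag. The region from 625 to 635 has a mean of 6.80 and the region from 4322 to 4328 a mean of -3.77.

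The authors' own fold changes, which the labels describe as made from pooled counts, were set beside the refitted ones. In the bacterium all 5230 identifiers of the authors' deposited table matched the count table, and fold changes of the 5146 tested genes correlated across genes at a Pearson r of 1 when rounded to 4 digits. The authors' deposited table listed 4105 bacterial genes under an adjusted p of 0.05, with 1976 higher, and 4039 of them were also called here, all in the same direction. In the diatom the protein identifiers of the authors' deposited table were lower by 343 than those of the count table. With that offset all 16822 matched, and fold changes of the 14100 tested genes correlated at a Pearson r of 0.996. Without it, 1306 identifiers matched, and the correlation over the 1113 of them that were tested was 0.0238. The authors' deposited table listed 2143 diatom genes under an adjusted p of 0.05, with 792 higher and 1351 lower. Of these, 1067 were among the 1266 called here, all in the same direction. Of the 50 diatom genes with the largest fold changes in the authors' deposited table, 48 had 0 counts in every library of one group and 49 had too few counts to be tested here. For Psemu1|283562 the authors' deposited table gave a log2 fold change of 2.95 with an adjusted p of 2.69e-24, and for SA11v2_00632 one of 8.26 with an adjusted p of 1.78e-99. The refit of separate cultures gave these genes edgeR adjusted p-values of 0.0052 and 5.53e-08. Pooled counts hold no spread between cultures, so p-values made from them do not measure it. Relative to the ratio of pooled counts, the diatom fold changes in the authors' deposited table were shifted by a median of 0.07, with 96.7% of 14099 genes within 0.01 of that shift. The bacterial fold changes in the authors' deposited table lay within 0.01 of the pooled ratio plus its median shift for 8.96% of 5143 genes. Against an edgeR fit of the separate cultures without a filter, a comparison chosen after seeing the data, this was 90.7% in the bacterium and 20.6% in the diatom.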

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

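Alternatives were chosen before the data were examined, except the subtraction of carry-over, the unfiltered fit set beside the authors' deposited table, and the recounts of runs and of shares of counts, which were chosen after seeing the data. The number of bacterial genes called stayed within 1.5 times of 4098 under all 14 alternatives, from 3394 with a 2-fold threshold to 4103 with carry-over subtracted. Each left-out culture kept 93.1% to 96.4% of the called genes in the same direction, and the count ranged from 3827 to 4047. The number of diatom genes called was 1266 and stayed within 1.5 times under 4 of 13 alternatives. It was 2138 with DESeq2 and 521 with a 2-fold threshold. Over the left-out cultures it ranged from 220 to 2290, and 17.2% to 92.2% of the called genes were kept; a fit without 1 culture has fewer samples, but why co-culture A lowers the count was not tested. No called gene of either organism changed sign under any refit, while with pooled ratios 99.8% of the bacterial calls kept their sign. The share of diatom calls that were higher moved from 35.5% to 23.8% with total count scaling, 19.8% without axenic culture A and 19.6% without axenic culture B. Whether the culture letters pair the cultures is not stated, and 3 cultures per group cannot settle it. Correlations of deviations for equal letters were 0.0726, 0.129 and -0.197 in the diatom and -0.0537, -0.0427 and -0.0165 in the bacterium. Not every culture correlated best with its own letter, though diatom B did (0.129 against 0.0832). With the letter as a replicate block the counts were 798 in the diatom and 3972 in the bacterium. All named genes kept their direction and, in each test, their side of the threshold. Carry-over subtracted, the log2 fold changes of SA11v2_00630, SA11v2_03903 and SA11v2_03904 were 9.65, -7.75 and -7.46, against 7.75, -6.36 and -5.93; that of SA11v2_00632 is not bounded, since 0 glucose counts were left. With pooled ratios in place of the refit, the correlation with the authors' deposited table was 0.9999 in the diatom, against 0.9963, and 0.9989 in the bacterium, against 1; with the unfiltered fit it was 0.9964 and, rounded to 4 digits, again 1. The cause was not tested. Not run were the run-type alternatives, since the table has 1 column per culture, and the alternatives for gene lists and for ribosomal and transfer RNA genes, since no product names were used. Low counts limit both named bacterial genes that fell, which had 3 (SA11v2_03903) and 9 (SA11v2_03904) counts over the co-cultures.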

Other observations

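The thinnings to equal depth and, for gene model classes, the odds ratio by expression and the shift per library were fixed before their results were seen, and the other tests below were chosen only after. Fold changes of tested bacterial genes correlated along the tag order, at r = 0.619 for neighbours, 0.396 at a distance of 2, 0.292 at 3, 0.203 at 5 and 0.137 at 10. Distance counts places among tested genes in tag order, so missing tags and untested genes were passed over. The highest values in 1000 shuffles were 0.0415, 0.0489, 0.0445, 0.058 and 0.0389, and the permutation p of 0.001 was at each distance the smallest these shuffles can give. In the diatom, 11538 gene models have names that carry 1 of 1588 numbers shared between models, and these numbers accounted for 14.8% of the variance of fold changes, against a shuffled mean of 13.8% (permutation p = 0.031, 1000 shuffles).

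Of diatom genes with at least 40 counts in some library and 0 in another, 31 in all, 9 had libraries at 0 in both groups. Psemu1|61123, chosen after its values were seen, had 0, 174 and 123 counts in axenic cultures A, B and C and 186, 0 and 0 in the co-cultures.

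With 6 cultures there are 10 ways to divide them into 3 and 3, too few for a share under 0.05. In the diatom 1 of the 10 splits, the real one, gave as many as 1266 genes, and the highest of the others gave 1. In the bacterium likewise 1 of the 10 gave 4098, and the highest of the others gave 0. Every other split mixes both conditions on each side, so a group difference would itself leave such splits few calls. Their low counts therefore do not weigh chance.

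The 18 abundant bacterial genes (log2 CPM above 5) that fell over 32-fold had 3980 summed CPM in co-culture A, 590 in B and 944 in C. A like number of counts from the glucose cultures in every co-culture library may account for it: summed raw counts were 7399, 6059 and 5179, a ratio of A to B of 1.22 against a depth ratio of 0.181, or 0.293%, 0.240% and 0.205% of the glucose counts. In that case the low depth of A would itself give the high CPM, and thinning B to that depth decides nothing, since it leaves expected CPM as it is (a ratio of A to B of 6.74 before, and 6.40 or more in 20 thinnings). Cells in the glucose state in co-culture A cannot be told apart from this, since the counts in A followed the glucose counts (Spearman 0.994 across these genes) under either. Subtracting the lowest share per library, a choice made after seeing the data, left 4103 bacterial genes called, 4092 of them among the 4098, while it moved the fold changes of all 4 named bacterial genes. The median CPM ratio of A to B was 5.52 in the 18 genes and 1.17 in abundant genes changed under 2-fold. In the 97 abundant genes that rose at least 32-fold it was 0.835. For C to B these ratios were 1.58, 1.1 and 0.861. The subtraction removed 3.21% of library A. A glucose-state share of that size, from libraries or cells, would not give the whole gradient, and its cause was not tested.

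Each diatom co-culture was placed on the genes called at least 2-fold without it, where 0 is the axenic mean and 1 the mean of the other co-cultures. Those genes were chosen on the same co-cultures that set position 1, so a left-out culture tends to fall below 1 by selection alone. On the log2 scale the median positions of A, B and C were 0.455, 0.804 and 1.19 for fallen genes. For risen genes they were 0.513, 0.802 and 0.651. On the linear scale they were 0.518, 0.968 and 1.14 for fallen and 0.55, 0.545 and 0.405 for risen genes. The linear values used library totals without TMM factors, so scale and normalization changed together. By the linear values A stood apart in fallen genes only, and whether the scale or the factors made that difference was not tested. Co-culture C was shallower than A (18983811 against 20426283 counts). Its position in fallen genes had an interquartile range of 1.00 to 1.41 around 1.19, against 0.252 to 0.679 for A. These positions share no scale, since A was placed on 723 fallen genes and C on 123. A also enters the mean that C was set against, so a low A raises C. On the first principal component, shared by all libraries, C lay at 46.4 and A at 9.30. Low depth alone thus did not bring a library near the axenic cultures. Thinning to equal depth, which leaves expected CPM as it is, gave A 0.475 over both directions and adds nothing. A share of axenic-state RNA in culture A could give its values, which differed by 0.032 between risen and fallen genes on the linear scale, but a weaker response of that culture would give the same, so these cannot be told apart. The selection of genes can also lower the position of A, by an amount that was not measured. No biological explanation was tested.

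Among called diatom genes, those of the fgenesh1_kg class were higher in 68.3% and other models in 28.5%. These shares were 56.6% and 17.9% with total count scaling, and 70.4% and 29.9% with RLE factors. Over the left-out cultures they ranged from 56.2% to 70.7% for the class and from 13.6% to 35.7% for other models. Expression level is argued against as the whole cause, since within 10 bins of expression the odds ratio was 5.55 (95% interval 4.04 to 7.62, over genes, which are not independent). A single culture as the whole cause is argued against too, since without each of the 6 cultures in turn the odds ratio was 3.82 or more and its 95% interval, again over genes, stayed at 2.46 or above. The median shift of the class against other models was 0.18, 0.10 and 0.28 on the log2 scale in co-cultures A, B and C, with a lowest value of 0.104, and 0.12, -0.03 and -0.10 in the axenic cultures, so co-culture B lay below axenic A. The shift had been fixed beforehand to weigh a single co-culture as the cause, and it decided neither way. What the class has in common is not given in the sources used here, and no biological explanation was tested.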
